A study of Gallus gallus with 6 samples.

How the data were processed

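RNA sequencing of breast muscle was done on an Illumina HiSeq instrument, per the labels' protocols, from tissue frozen in liquid nitrogen. The submitters' processing notes name FastQC, TopHat2 2.0.9, HISAT2 and StringTie 1.3.0 and the chicken genome build galGal5. These tools were available here only as a list of names and versions, without order or role. The tool that made the deposited table is not given in the sources used here. The authors deposited 1 table of the whole series, named as a table of FPKM, the fragments of a transcript scaled to its length and to the mapped fragments of the library. What was used from it was only the gene names and row identifiers that the authors deposited with the values, and which cells were filled.

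The 6 samples were placed in group II (3 samples) and group IV (3 samples) from their titles. The table holds 9 columns of per-library values that were not used. Of these, 6 stand under library names that match no label, and 3 stand in a further block under the first 3 of those names with a suffix. That block has its own row identifiers, which fill 24102 of the 24682 rows. It was not tested whether the block repeats the first 3 library columns, so it is not taken as further measurements. Whether it is laid out row for row like the rest of the table was also not tested. In addition, 3 rows hold stray entries in columns without a name. The row count was taken from the first column of gene names, and blank names in that column were not looked for. Whether the values stand beside the right names was not tested. A library column was to be used only where its name matched the labels of 1 sample or of 1 group, and column order or expression values were not taken as evidence. No column met this rule.

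Before the data were examined, a test was fixed of group IV against group II with limma on log2(FPKM + 1). Fixed with it were tests of the gene lists, a permutation test of list levels per library and a rule for the genes to be named. The replicate number as a block was an alternative fixed for the gene test. None of these was run, because no column of the table could be tied to a library of known diet. No p-value, fold change or expression level was computed for the text.

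The gene names were counted with Python 3.11.15 and pandas 2.3.3. A name was counted as a locus number where LOC was followed only by digits. It was counted as a date where it had the form of a day and the month Mar or Sep. Of the 24682 rows, 18465 carried a name that is a symbol of the RefSeq gene table of the chicken assembly GRCg7b, and a further 321 carried a synonym listed there. The 18465 include rows named by a locus number, since that gene table also lists such names as symbols. That assembly differs from the build named in the submitters' notes, so none of its coordinates was used. The 29 gene lists, written before the data were examined, were matched to the row names by exact symbol or listed alias. The precision of any expression value is limited by depth, which is unknown here.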

Results

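Breast muscle, the main flight muscle and the largest edible muscle of the chicken, was sampled from Gushi chickens, a Chinese breed, at 48 weeks of age, and its total RNA was sequenced. The series held 6 libraries in 2 diet groups of 3. Group II, which the sample titles also called the control, received a high-energy, low-protein diet, for which the labels gave a crude protein content of 14.51%, and an energy value without the amount of feed it refers to. Group IV received the basic diet, whose energy and protein content the labels did not state. Both groups were fed what the labels call biological grass, so the comparison is between diets that both include it and does not test the grass.

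The comparison the design implies is group IV against group II, 3 libraries against 3. It was not made. The 6 library columns of the deposited expression table carry running names that occur in none of the labels, and no name in the table ties a column to a diet. The columns stand in 2 blocks of 3 and 3, each behind its own column of gene names, which matches the sizes of the diet groups but does not say which block is which diet, or that the blocks are the diets. Assigning the columns by their order would have fixed the direction of every difference without evidence. No gene is therefore described as higher or lower in either diet, and no expression level is given, since columns whose names match no label were not used for any value, pooled values included. The sequencing depth of each library is unknown here.

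The table listed 24682 rows under 24422 distinct names. Of these rows, 15433 carried a name that was not a locus number, an XLOC identifier or a date. This class holds names such as gene symbols, 444 of them microRNA symbols. How many of its names are gene symbols was not counted separately. A further 8393 rows were named by a locus number (LOC), and 835 rows carried an XLOC identifier. In 21 rows the name was a calendar date in the first name column, and in 21 of these 21 the second held the same date as a spreadsheet day number. A spreadsheet makes such entries from gene symbols that read as a month and a day. The original symbols of these rows therefore stand in neither name column, and these rows are not among the 15433. The 2 name columns were identical in all other rows. There were 77 names carried by more than 1 row, so such a name does not point to a single row. Names alone do not show that a gene was expressed in the muscle.

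Of the 811 distinct genes in 29 lists chosen for this tissue and these diets, 745 had a row under their symbol or a listed alias. The others had no such row, and no gene was analysed beyond its name. For lipid supply and storage, a row was found for 20 of 20 genes of fatty acid synthesis, among them FASN, the fatty acid synthase, and SCD, the stearoyl-CoA desaturase. A row was also found for 11 of 11 lipolysis genes, 14 of 15 adipocyte markers, 28 of 33 genes of fatty acid oxidation and 13 of 17 genes of triglyceride synthesis and lipid droplets. For protein turnover, a row was found for 30 of 33 genes of muscle atrophy and autophagy, including FBXO32, a muscle ubiquitin ligase, for 29 of 35 proteasome genes and for 28 of 32 genes of the response to amino acid deprivation, including ASNS, the asparagine synthetase. For muscle fibres and their fuel, a row was found for 16 of 22 fast fibre markers, 20 of 21 slow fibre markers and 32 of 38 genes of glycolysis and glycogen. The fast fibre markers without a row were ATP2A1, MYBPC2, MYH1, ACTN3, CASQ1 and RYR1. Those of glycolysis and glycogen without a row were ALDOA, PGAM2, ENO3, PYGM, GYS1 and SLC2A3. Why these names had no row was not tested. Of the red blood cell genes, 16 of 22 had a row. These counts describe names only: a filter on low values would leave fewer genes to compare, and the counts hold no measurement of the birds.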

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

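No paired analysis was possible because the library columns carry no replicate number and no group. The sample titles number the replicates within each group and do not say that equal numbers belong together. A pairing of the birds would therefore not be known from the titles even with named columns. The replicate block and other list tests fixed for the comparison of the diets were not run, since each needs the diet behind each column. Other pseudocounts, filters, scalings, library weights, left-out libraries and thresholds were also not tried, because columns whose names match no label were not used for any value. The match of the 811 listed genes to the row names was repeated with settings chosen after seeing the data. The 745 genes with a row became 727 with symbols alone, without the listed aliases, and 758 when the synonyms of the RefSeq gene table were searched as well.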
